A study of Mus musculus with 82 samples.

How the data were processed

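RNA was measured in 82 individual untreated mammary tumours of 13 mouse models, 2 to 12 libraries each. Per the labels' protocols, cryopreserved tumours were homogenized, RNA was isolated with RNeasy Mini columns and checked on a Bioanalyzer, and TruSeq mRNA libraries were sequenced. The labels call the tumours individual and the libraries biological replicates, but do not say whether the libraries of a model come from separate animals or from passages of 1 tumour, so p values measure the spread among these libraries, which can be technical. Strain is nested in model, and strain variants against mm10, a C57BL/6 reference, were not examined.

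The deposited gene table holds expected counts (estimated counts per gene), of which 85.5% of values are whole and 52.7% are 0 among 47480 genes. STAR, SAMtools, Picard and Salmon were named with no version and with build mm10, per the submitters' processing notes. The second deposited table holds the authors' normalized signal. By its values it is each count divided by the 75th percentile of the library's non-zero counts, times 1000, with 1 for each 0. Zeros so rank above 11% of the non-zero values. Neither table has mitochondrial genes. Pseudogenes on chr1 that resemble mitochondrial genes (Gm10925, Gm28661, Gm28437, Gm29216) took 1.09% to 3.64% of counts, 18S 0.00623% to 1.66% and hemoglobin at most 0.293%. Strand was not stated, so overlapping genes such as Igf2 and Igf2os cannot be told apart. All columns matched the labels. Gene positions are from GENCODE M21 on mm10.

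Counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by model (minimum count 10, minimum total 15) kept 22847 genes, TMM factors scaled the libraries, and robust quasi-likelihood fits of 1 mean per model over all 82 libraries left 69 residual degrees of freedom. The comparisons were the F test among the 13 models, each model minus the unweighted mean of the other 12 model means on the log2 scale, and 3 pairs of models. Calls needed a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is from edgeR unless another tool is named beside it. SEs are the log2 difference divided by the square root of F. For genes at 0 in the compared models the fitted difference is no bound, so levels and the next-highest model are given, with a bound of 3 counts over the summed depth where all libraries of a model are at 0. These bounds cover counting error only. A model with 1 library left by leaving out the other is assumed to vary like the rest.

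Gene lists (38, of up to 24 genes) were fixed before the data were examined: luminal, hormone sensing, milk protein, basal, squamous, T cell, B cell, plasma cell, natural killer, macrophage, neutrophil, dendritic, mast, endothelial, fibroblast, adipocyte, muscle and blood cell markers, and junction, epithelial-mesenchymal transition, proliferation, DNA replication, DNA repair, interferon, antigen processing, class II, checkpoint, neutrophil attractant, monocyte attractant, hypoxia, p53, Wnt, Notch, ERBB, immediate early, heat shock, cholesterol and fatty acid genes. Each list with at least 5 measured genes was tested by camera (limma 3.58.1, voom) with estimated inter-gene correlation, adjusted over all 608 pairs of list and comparison, so an adjusted p of a list is from camera. The camera preset correlation of 0.01 was an alternative. A list score is the mean log2 CPM of its members (prior count 2). The lists described for a comparison were chosen after seeing the list results.

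Named genes followed a rule fixed before the data were examined: Trp53, Brca1, Erbb2 and 14 further subtype genes. Per model the rule took the 6 largest increases (mean of at least 5 CPM) and the 4 largest decreases (mean of the others at least 5 CPM) that passed and stood on 1 side of the mean of the other models' means in every library. Per pair it took the 10 largest each way with no overlap between libraries, and per described list up to 4 members. Predicted genes, receptor segments and pseudogenes were skipped where their names show them, which kept the annotated pseudogene Kdm4dl, and a few genes that the rule names are not reported here. Met, Capza2, Smo, Cdkn2a, Ccnd1, Fgfr1, Mdm2, Frs2, Dnmt3a, Asxl2, Rab10, Xist, Cdkn2b, Tes, Cav1, Impdh1 and Nf1 were chosen after their values were seen.

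The tests were tested on simulated data with 200 changed genes per fold: for 2208 (n = 12) 63% of 2-fold and 88% of 4-fold changes were recovered with 0.25% of unchanged genes called, and for KPB1-A (n = 2) 32%, 61.5% and 0.098%. The simulated models otherwise shared the same mean for each gene, apart from a changed list, whereas 98.2% of real genes differed among models. False calls under such wide differences were therefore not tested. The same genes were changed in 2208 and KPB1-A, so each model also shifted the reference of the other. Alternatives fixed before the data were examined were DESeq2 size factors, no filter, DESeq2 1.42.0, limma on the log2 of the authors' table, a block for library number (below 3000 or not), a reference of the same strain, fits of only the 2 models of a pair, leaving out each library of models with 2 to 5, leaving out the 2208 library without a number, and camera with the preset correlation, the authors' table, the block and the same-strain reference. A reference without T12 and E0771 was chosen after seeing the data. Groups were relabelled at random as a check of the counts. DNA was not measured.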

Results

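RNA sequencing of 82 untreated mouse mammary tumours covered 13 models: 2208 (n = 12 libraries), 2250 (n = 11), 2225 (n = 10), MMTV-NEU (n = 8), 2153 (n = 7), 9263 (n = 7), 2336 (n = 5), 4T1 (n = 5), MMTV-PYMT (n = 5), 2224 (n = 4), E0771 (n = 3), T12 (n = 3) and KPB1-A (n = 2). The tumours grew on 3 strains, BALB/c for 64 libraries, FVB for 15 (MMTV-NEU, MMTV-PYMT and KPB1-A) and C57BL/6 for the 3 of E0771, so strain could not be separated from model. Counts per library summed to between 14.44 M and 132.7 M with a median of 58.2 M, and 19597 to 24209 genes had a count. Per model the totals were 29.43 to 119.8 M (2153), 14.44 to 132.7 (2208), 35.22 to 93.02 (2224), 17.16 to 97.55 (2225), 21.27 to 67.62 (2250), 18.04 to 81.12 (2336), 76.71 to 108.6 (4T1), 23.39 to 116.4 (9263), 57.68 to 76.32 (E0771), 40.82 to 45.41 (KPB1-A), 17.24 to 89.73 (MMTV-NEU), 39.73 to 73.41 (MMTV-PYMT) and 73.8 to 86.71 M (T12). The 10 largest genes took 4.79% (a library of E0771) to 12.5% (a library of MMTV-NEU) of the counts, and 81 of 82 libraries correlated best with a library of their own model. Levels below are mean CPM ± SD over libraries, and changes are log2 differences ± SE with adjusted p from edgeR. The genes that open the description of a model stood on 1 side of the other models' mean in each of its libraries, whereas list members needed only the adjusted p. A gene named as low in a model can be as low or lower in another model.

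The 13 models were compared first for Erbb2, Trp53, Brca1 and the subtype genes fixed before the data were examined. Erbb2, the receptor tyrosine kinase named by the MMTV-NEU transgene (chr11 98412470-98437716, mm10), reached 11900 ± 3910 CPM in MMTV-NEU (n = 8) against 23.3 (T12) to 151 CPM (9263) elsewhere, a log2 difference of 7.29 ± 0.10 (adjusted p = 7.59e-66). The labels do not state the species of this transgene, and reads of a rat gene count here only where they resemble mouse Erbb2. Trp53, which stops damaged cells from dividing (chr11 69580359-69591873), was lowest in KPB1-A at 17 ± 9.46 CPM (n = 2; -2.92 ± 0.32, adjusted p = 2.36e-12) and ran from 68.7 (4T1) to 317 ± 126 CPM (9263) in the other models. Brca1 (chr11 101488764-101551955), a DNA repair gene, ran only from 18.7 CPM in 4T1 to 67.8 CPM in 2153. The tight junction gene Cldn3 was near 0 in T12 (0.0915 ± 0.0976 CPM, n = 3) and E0771 (0.106 ± 0.0666, n = 3), 13.8 ± 8.35 in 9263, 60.1 ± 20.2 in 4T1 and up to 595 ± 268 CPM in 2224.

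**Figure D1:**
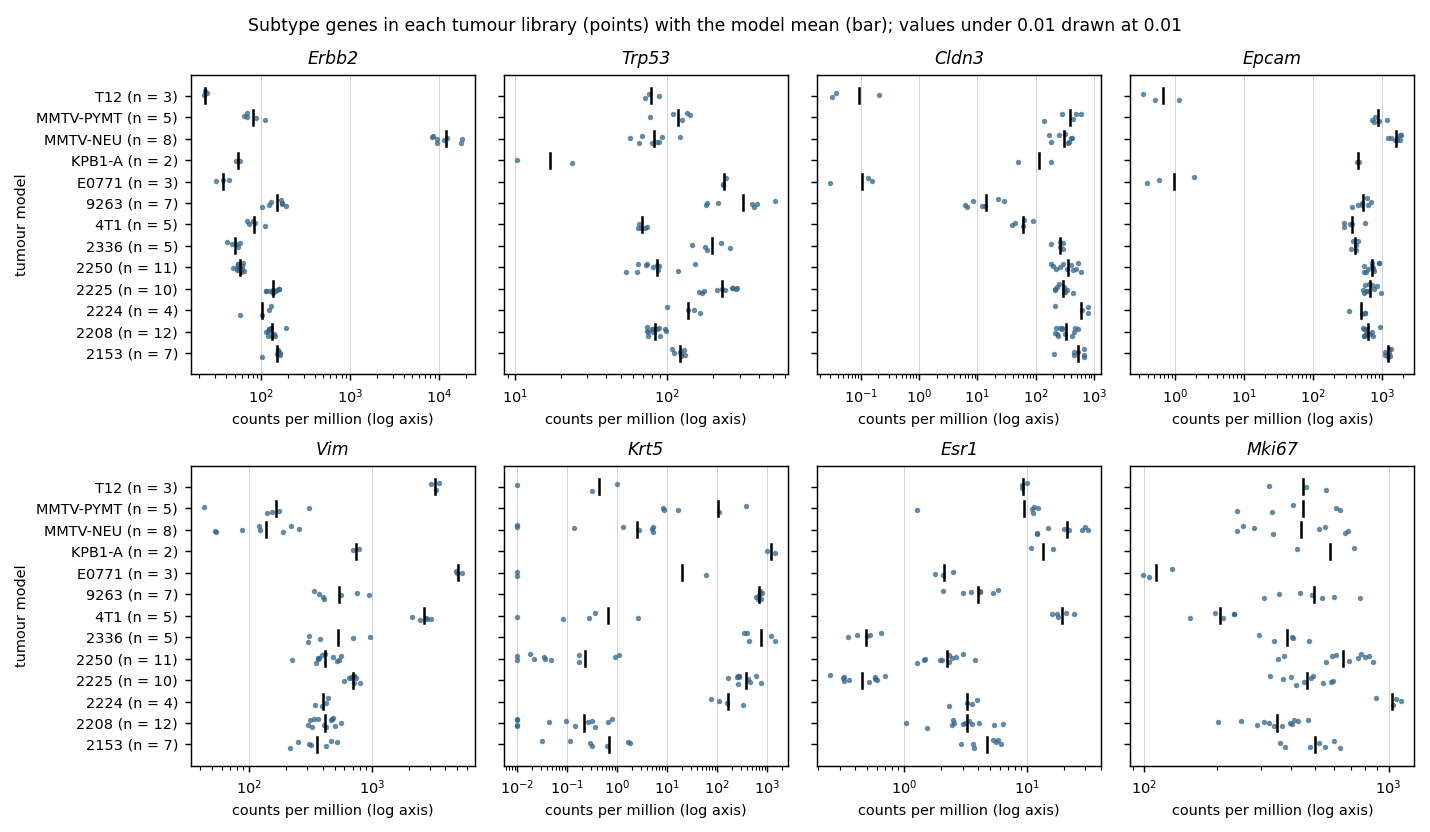
CPM on a log axis of Erbb2, Trp53, Cldn3, Epcam, Vim, Krt5, Esr1 and Mki67 in each of the 82 libraries, 1 point per library and a bar at the mean of each of the 13 models, with values under 0.01 drawn at 0.01. Erbb2 averaged 11900 CPM in MMTV-NEU, Trp53 17 CPM in KPB1-A, and Epcam 0.66 CPM in T12 and 0.948 CPM in E0771.

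Other subtype genes differed among the models too. The adhesion gene Epcam fell in T12 (0.66 ± 0.413 CPM, -9.17 ± 0.38, adjusted p = 2.33e-33) and E0771 (0.948 ± 0.809 CPM, -8.58 ± 0.37, adjusted p = 2.02e-32) and stood at 366 (4T1) to 1610 ± 236 CPM (MMTV-NEU) elsewhere. The mesenchymal filament gene Vim was highest in E0771 (5090 ± 283 CPM), T12 (3300 ± 235) and 4T1 (2650 ± 364) and lowest in MMTV-NEU (138 ± 76.4) and MMTV-PYMT (165 ± 96.1). The basal keratin Krt5 was highest in KPB1-A (1210 ± 288 CPM), 2336 (758 ± 508) and 9263 (701 ± 64.7), and Krt14 in 9263 (378 ± 142) and 2225 (300 ± 74.4). Esr1, the oestrogen receptor, was highest in MMTV-NEU (21.3 ± 7.89 CPM) and 4T1 (19.4 ± 3.33) and lowest in 2225 (0.457 ± 0.157) and 2336 (0.491 ± 0.113). Egfr was highest in MMTV-NEU (110 ± 22.5 CPM) and MMTV-PYMT (101 ± 47.9) and lowest in 2153 (5.95 ± 2.69), and the proliferation gene Mki67 ran from 112 ± 16.6 CPM in E0771 to 1030 ± 100 in 2224. By the F test of edgeR, 22438 of 22847 genes (98.2%) differed among models, and 22378 to 22449 did so with 1 library left out. Every measured member differed in 37 of the 38 gene lists, the endothelial list (15 of 16 members) being the exception.

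**Figure D2:**
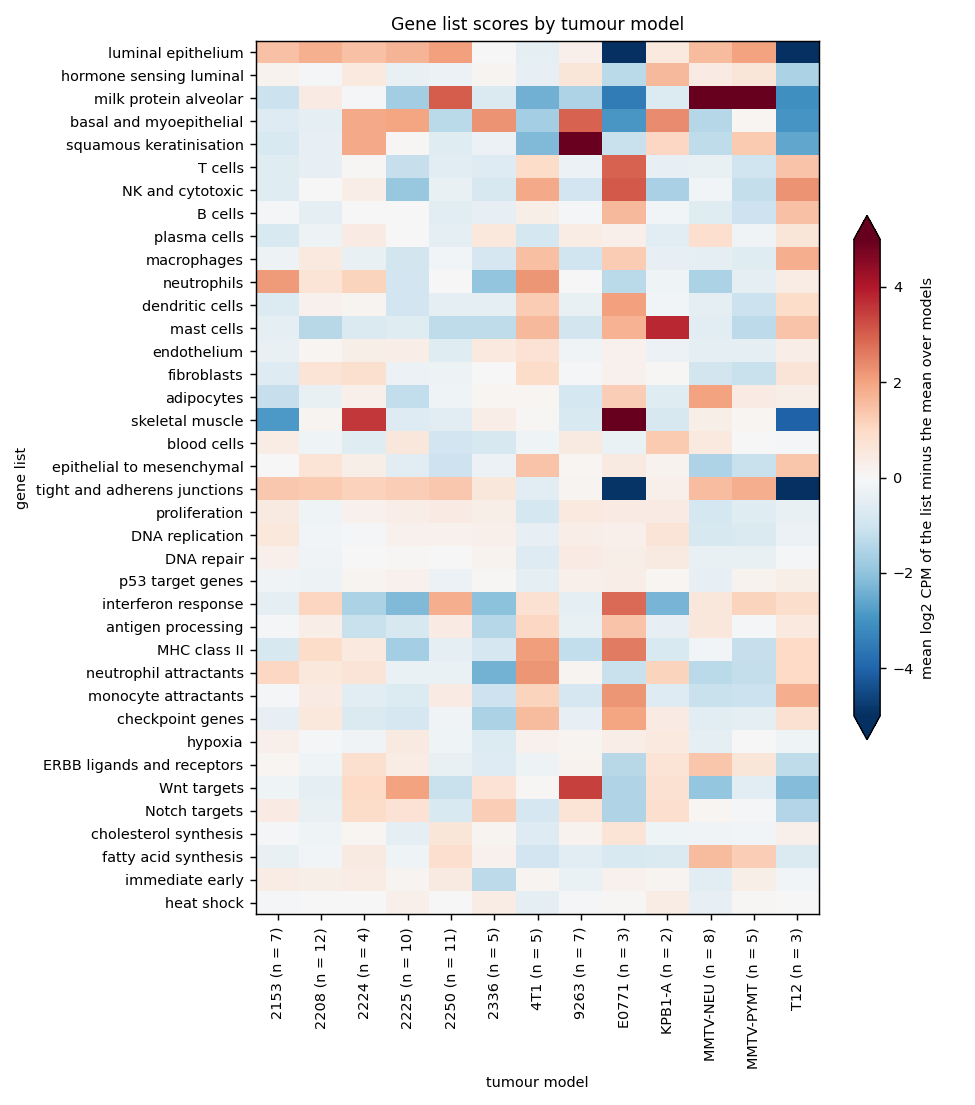
Mean score of each of 38 gene lists (vertical axis) in each of the 13 models (horizontal axis), drawn as the mean log2 CPM of the list's members minus the mean over models, with colours limited to 5 log2 units each way. Milk protein scores averaged 7.60 in MMTV-NEU and 6.58 in MMTV-PYMT, and squamous scores 4.33 in 9263.

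Neighbouring fibroblast growth factor genes set 2153 (n = 7) apart. Fgf4, a growth factor of the early embryo (chr7 144847367-144865243), averaged 411 ± 66.2 CPM in 2153 and at most 0.0581 CPM (KPB1-A) in the other 12 models, a rise of 16.47 ± 0.16 (adjusted p = 6.54e-61). Its neighbours Fgf15 (139 ± 26.3 CPM, 17.1 in 2224) and Fgf3 (17.5 ± 2.09 CPM, 0.387 in KPB1-A), a growth factor gene known as an insertion site of mouse mammary tumour virus, rose by 10.80 ± 0.31 and 10.63 ± 0.33 (adjusted p = 2.91e-43 and 7.95e-37). The growth factor Igf2, also on distal chr7 (142650766-142666816), reached 3980 ± 379 CPM against 440 in 9263 (9.27 ± 0.45, adjusted p = 6.94e-30), with its overlapping transcript Igf2os at 60.8 ± 31.5 CPM and the meiotic gene Fkbp6 at 24 ± 3.4 (18.4 in 2224). The p53 relative Trp73 was at 0.00293 CPM (63.7 in 9263), the BMP and Wnt antagonist Sostdc1 at 0.00452, and the muscle kinase Ckm (-6.86) and Bex1 (-5.87) fell. The cyclin gene Ccnd1, read after its neighbours were seen, was at 6540 ± 1300 CPM in 2153 against 1050 in 4T1 as the next model (3.95 ± 0.13).

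Among lists in 2153, 17 of 20 junction genes rose and 1 fell (17 and 1 adjusted over the list alone). Cldn3 rose to 523 ± 172 and Cldn8 to 44.2 ± 8 CPM. Of 19 luminal genes 17 rose and 2 fell (17 and 2 adjusted over the list alone), the stem cell marker Prom1 to 268 ± 29.4 CPM (4.27 ± 0.19, adjusted p = 2.07e-32). Neutrophil genes rose in 16 of 18 and DNA replication genes in 16 of 19 (16 and 16 adjusted over the list alone). S100a9 rose to 82.3 ± 61.6 CPM (4.58 ± 0.35) and Mcm7 to 315 ± 64 CPM (1.13 ± 0.09). Antigen presentation genes of class II fell in 7 of 10 (8 adjusted over the list alone). Cd74 fell to 104 ± 69.8 CPM (-1.36, adjusted p = 0.0251). By edgeR 12129 genes passed, 6728 higher and 5401 lower. None of the 38 lists passed camera with estimated correlation and 3 had unadjusted p under 0.05 (junction adjusted p = 0.0707, luminal 0.0971, neutrophil 0.377, DNA replication 0.877, class II 0.97). The junction and luminal lists passed only with the preset correlation.

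The 2 largest named increases in 2208 (n = 12) were on chr6. Cftr, an epithelial chloride channel (chr6 18170687-18322768), averaged 402 ± 39.3 CPM against 22.7 in T12 as the next model (11.01 ± 0.25, adjusted p = 5.04e-46). Fezf1, a zinc finger gene of the developing brain (chr6 23245044-23248362), averaged 77 ± 24.7 CPM against 5.93 in 2336 (10.27 ± 0.27, adjusted p = 4.84e-45). The fibrinogen chain Fgg (76.9 ± 60.4 CPM, 2.36 in KPB1-A), the ALK ligand Fam150b (299 ± 101, 108 in 2250), Mageb16 (5.7, 5.69 in 2250) and Dmrt3 (8.02, 33 in 2336) were also high. Krt5 was low at 0.223 ± 0.267 CPM (-6.46 ± 0.81, adjusted p = 1.51e-10), with Sorcs1 (-7.07), the B cell coactivator Pou2af1 (0.0447 CPM, 103 in 9263) and Irx4 (0.0324 CPM, 142 in 9263). Krt5 was about as low in 2250 (0.23 CPM), T12 (0.445), 4T1 (0.668) and 2153 (0.696). The growth factor receptor gene Met (chr6 17463800-17573980), read after Cftr was seen, was at 4420 ± 848 CPM in 2208, 9520 ± 1250 in T12, 2540 ± 723 in 2250 and 21.1 to 136 elsewhere.

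Luminal genes rose in 18 of 19 and fell in 1 in 2208 (18 and 1 adjusted over the list alone). The mucin Muc1 rose to 275 ± 117 CPM (5.42 ± 0.16, adjusted p = 1.38e-42, 71 in MMTV-PYMT), while Krt19 fell to 1.16 ± 1.43 CPM. Junction genes rose in 18 of 20 (18 adjusted over the list alone), Cldn7 to 221 ± 73.5 CPM (3.22 ± 0.14) and Cldn4 to 223 ± 79.5. Interferon response genes rose in 20 of 24 and checkpoint genes in 8 of 13 (20 and 8 adjusted over the list alone). Cxcl10 rose to 20.8 ± 8.17, Isg15 to 49.7 ± 25.8 and Cd274, which encodes PD-L1, to 16.6 ± 11.4 CPM. Muscle genes rose in 14 of 15 (15 adjusted over the list alone) unevenly, with scores from -2.3 to 8.48 per library and Ckm at 105 ± 246 CPM. By edgeR 12375 genes passed, 6726 higher and 5649 lower. Camera passed the luminal and junction lists (adjusted p = 0.0274 for both) and not the interferon (0.877), checkpoint (0.789) or muscle (0.985) lists. Both calls ended with the same-strain reference (0.0518 and 0.0576) and without T12 and E0771 in the reference (0.746 and 0.894), and the muscle gene Myh4 (165 ± 424 CPM) turned to -0.28 with limma on the authors' table.

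Next was 2224 (n = 4). The long intergenic RNA Etos1 (chr7 130770638-130772652) averaged 49.5 ± 3.41 CPM against at most 0.179 (E0771; 13.61 ± 0.24, adjusted p = 1.74e-29). Tg, the thyroid hormone precursor (chr15 66670753-66850721), averaged 78.7 ± 3.07 CPM against 1.31 in MMTV-NEU (8.59 ± 0.32, adjusted p = 9.87e-37). Fgf8, an embryonic growth factor and another viral insertion site of mouse mammary tumours, averaged 69.7 ± 19.5 CPM, with 58.1 in 2336 (11.20 ± 0.30, adjusted p = 2.41e-45). The lysozyme Lyz1 (305 ± 64 CPM, 8.36 in T12; 8.05 ± 0.55), Kctd19 (9.68 CPM) and Fkbp6 (18.4 ± 7.89) were high. The milk protein gene Lalba (0.177 CPM, -4.28 ± 1.01, adjusted p = 0.000343), Pax9 (0.0515 CPM, -4.16), Igf2bp1 (0.0363 CPM, -3.92) and Igf2os (0.0195 CPM, -3.80) were low. Each was lower still in another model (0.0288, 0.00197, 0.00194 and 0.00552 CPM), so none of them marked 2224 alone. Mdm2, which degrades p53 (chr10 117688875-117710758), and its neighbour Frs2 (chr10 117069427-117148534) were read later and stood at 947 ± 79 and 676 ± 85.1 CPM against 43.5 to 97.2 and 26.4 to 74.9 elsewhere (Mdm2 3.80 ± 0.07).

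Basal genes rose in 12 of 18 in 2224 (12 adjusted over the list alone). The differentiation inhibitor Id4 rose to 451 ± 127 CPM (5.67 ± 0.24, adjusted p = 3.58e-33, 611 in 2336), Oxtr to 30.6 ± 10.8 and Krt5 to 167 ± 111. Interferon response genes fell in 23 of 24 and antigen processing genes in 9 of 12 (23 and 9 adjusted over the list alone). Usp18 fell to 1.77 ± 0.333, Nlrc5, which drives class I genes, to 3.77 ± 1.7 (-2.74 ± 0.35, adjusted p = 7.94e-10) and Tap1 to 17.8 ± 3.13 CPM. Squamous genes rose in 12 of 17 and fell in 1 (12 and 1 adjusted over the list alone; 9 and 2 without replicate 4), Sprr1b at 15.6 ± 30.6 (8.73) and Krt6b at 32.1 ± 62.8 CPM (7.36). Replicate 4 carried most of both levels, and without it Sprr1b was at 2.84 (adjusted p = 0.00615) and Krt6b at 1.81 (adjusted p = 0.0901). Muscle genes rose in 11 of 15 (13 adjusted over the list alone). Acta1 rose to 257 ± 221 and Myh4 to 170 ± 173 CPM. Only 1 muscle gene rose without replicate 1 and 2 without replicate 3, Acta1 being at 2.86 (adjusted p = 0.111) and Myh4 at 3.61 (adjusted p = 0.052) without replicate 1. By edgeR 8852 genes passed, 5475 higher and 3377 lower, and 7202 to 8331 with 1 library left out. Camera passed 0 of 38 lists, with 6 at unadjusted p under 0.05 (basal adjusted p = 0.159, antigen processing 0.319, interferon 0.877, squamous 0.885, muscle 0.917).

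2225 (n = 10) was marked by Brinp2, a gene of the nervous system (chr1 158245269-158356326), and Ren1, the renin gene (chr1 133350510-133360325). Brinp2 averaged 175 ± 38.2 CPM against 0.471 in 9263 (12.68 ± 0.19, adjusted p = 2.18e-62) and Ren1 325 ± 25.9 CPM against 1.22 in MMTV-PYMT (12.40 ± 0.41, adjusted p = 3.81e-40). The reproductive homeobox gene Rhox5 (384 ± 144 CPM, 221 in E0771), the Wnt potentiator Rspo4 (51.3 ± 12.6, 12.7 in 9263; 10.03 ± 0.33), the Wnt antagonist Dkk4 (9.53 ± 3.9, 43.7 in 9263) and Gp2 (9.87 ± 7.66) were also high. The actin severing gene Scin (0.0191 CPM, 17.5 in T12; -7.31 ± 0.56, adjusted p = 1.65e-19) and the signalling regulator Rgs20 (0.0519 CPM, 55.1 in 2250; -7.22 ± 0.28, adjusted p = 3.92e-36) fell, with Adcy8 (0.00786 CPM) and Tmem229a (-7.39). The DNA methyltransferase Dnmt3a (chr12 3806007-3914443), read after a run of low genes on chr12 was seen, was at 6.06 ± 1.37 CPM against 48.6 to 163 elsewhere (-3.69 ± 0.11), beside Asxl2 (2.62 ± 0.682, 25.5 to 110) and Rab10 (10.9 ± 2.19, 94.3 to 335).

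In 2225 the Wnt genes rose in 12 of 16 and fell in 3 (12 and 3 adjusted over the list alone). The ligand Wnt6 rose to 298 ± 70.4 CPM (8.70 ± 0.32, adjusted p = 1.59e-37, 71 in 9263) and the feedback inhibitor Nkd1 to 320 ± 60.6 (6.12 ± 0.25, adjusted p = 5.73e-35, 109 in the next model). Basal genes rose in 13 of 18 and fell in 3 (13 and 3 adjusted over the list alone). Krt5 rose to 371 ± 182, Krt17 to 172 ± 38.6 and Cdh3 to 203 ± 21.1 CPM. All 24 interferon response genes fell (24 adjusted over the list alone), Ifit1 to 1.06 ± 0.545 CPM (-4.13 ± 0.45, adjusted p = 6.11e-13) and Mx1 to 0.88 ± 0.416. Natural killer genes fell in 12 of 13 (12 adjusted over the list alone). Gzmb fell to 0.125 ± 0.143 CPM (-3.81 ± 0.70, adjusted p = 2.26e-06) and Ccl5 to 0.424 ± 0.211. Macrophage genes fell in 15 of 18 and rose in 1 (16 and 1 adjusted over the list alone). Adgre1 fell to 6.85 ± 2.88 CPM (-1.86). By edgeR 13938 genes passed, 7815 higher and 6123 lower. None of the 38 lists passed camera with estimated correlation and 4 had unadjusted p under 0.05 (Wnt adjusted p = 0.324, basal 0.377, natural killer 0.807, interferon 0.841, macrophage 0.918).

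The 2 largest named increases in 2250 (n = 11) were Pip and Lalba. Lalba, a milk protein gene (chr15 98480400-98482721), averaged 5070 ± 1860 CPM against 940 in MMTV-NEU (11.90 ± 0.44, adjusted p = 3.36e-37), and Pip, a secreted protein of mammary and salivary glands (chr6 41847535-41852065), 181 ± 69.6 CPM against 6.5 in MMTV-PYMT (12.96 ± 0.54, adjusted p = 8.11e-30). Dpp10 (52.1 ± 17.3 CPM, 6.91 in MMTV-NEU), the neuronal filament gene Ina (56.8 ± 7.49, 7.87 in 2153), C2cd4a (33.5 ± 25.4) and RP23-278M8.1 (27.7) were high. The homeobox gene Dlx2 (79.3 CPM in 2153) and Zic2 (66 in 2336) had 0 counts in all 11 libraries, bounded by 0.00552 CPM, and Pax9 (0.00197 CPM) and Sostdc1 (0.00551, 96.5 in KPB1-A) were close to 0. Met was at 2540 ± 723 CPM (4.53 ± 0.11) while its neighbour Capza2 (chr6 17636234-17666972) fell to 55.5 ± 5.4 CPM (-2.30 ± 0.08), and the hedgehog receptor Smo reached 2800 ± 229 CPM against 759 in T12.

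All 19 luminal genes rose in 2250 (19 adjusted over the list alone). The epithelial transcription factor Elf3 rose to 272 ± 51 (3.74 ± 0.14, adjusted p = 2.54e-36) and Ehf to 620 ± 129 CPM. Milk genes rose in 12 of 15 and fell in 1 (12 and 1 adjusted over the list alone), Csn3 to 2690 ± 2400 (23600 in MMTV-NEU) and Btn1a1 to 61.8 ± 34.1 CPM. Interferon response genes rose in 22 of 24 (22 adjusted over the list alone), Oas2 to 151 ± 78.9 CPM (3.65 ± 0.29, adjusted p = 1.79e-18, 119 in MMTV-PYMT) and Oasl1 to 78.1 ± 25. Genes of epithelial-mesenchymal transition fell in 15 of 22 and rose in 2 (15 and 2 adjusted over the list alone). Sox9, a stem cell regulator, fell to 1.37 ± 0.804 CPM (-6.24 ± 0.29, adjusted p = 8.86e-31, 49.7 to 262 elsewhere) and Twist1 to 1.51. Basal genes fell in 14 of 18 and rose in 2 (14 and 2 adjusted over the list alone). Krt5 fell to 0.23 ± 0.392 CPM (-6.45) and Id4 to 0.577 ± 0.204, while Sox10 rose to 1130 ± 320 CPM (3.54 ± 0.15). By edgeR 13657 genes passed, 7333 higher and 6324 lower. Camera passed the luminal list (adjusted p = 0.0374) and not the milk (0.377), interferon (0.805), transition (0.918) or basal (0.918) lists, and the luminal call ended with the same-strain reference (0.14) and without T12 and E0771 (0.746).

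The largest named increase in 2336 (n = 5) was that of Grin2b. Grin2b, a glutamate receptor subunit of neurons (chr6 135713233-136173511), averaged 61.3 ± 49.4 CPM against 0.0155 in MMTV-PYMT (13.83 ± 0.35, adjusted p = 7.85e-34). Hoxd13, which patterns the limb tip, averaged 32.8 ± 9 CPM against 0.077 in 2225 (12.54 ± 0.37, adjusted p = 2.43e-28), and Fgf8 58.1 ± 7.98 CPM (10.91 ± 0.29, adjusted p = 1.46e-45). The developmental regulators Nkx2-5 (9.35 ± 8.56 CPM), Nkx6-1 (14.5 ± 2.97, 1.14 in KPB1-A) and Dmrt3 (33 ± 10.7, 8.02 in 2208) were also high. Hhip, the hedgehog inhibitor, had 0 counts (bound 0.0103 CPM) against 92.5 in 4T1, the protease Mmp10 was at 0.0139 CPM (25.5 in 4T1), and the basement membrane gene Col4a5 (250 CPM in 2208; -6.41 ± 0.41, adjusted p = 1.82e-23) and Zfp239 (0.17 CPM, -6.58) fell. The receptor gene Fgfr1 (chr8 25513654-25575718), read after a run of high genes on chr8 was seen, was at 5990 ± 756 CPM against 1970 in 2224 as the next model (3.78 ± 0.13).

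Basal genes rose in 12 of 18 and fell in 1 in 2336 (12 and 1 adjusted over the list alone). Id4 rose to 611 ± 55.5 CPM (6.14 ± 0.23, adjusted p = 3.21e-36), Krt5 to 758 ± 508 (6.09 ± 0.55) and Myh11 to 169 ± 166. Neutrophil attractants fell in 10 of 11 (10 adjusted over the list alone). The granulocyte growth factor Csf3 fell to 0.0459 ± 0.0467 CPM (-4.97 ± 0.74, adjusted p = 1.97e-08), Cxcl2 to 0.123 (-3.60) and Cxcl3 to 0.00344. Neutrophil genes fell in 11 of 18 and rose in 2 (11 and 2 adjusted over the list alone). S100a8 fell to 0.096 ± 0.042 CPM (-5.91), whereas Camp rose to 2.27 ± 3.34. Checkpoint genes fell in 11 of 13 (12 adjusted over the list alone). Cd274 fell to 1.1 ± 0.242 CPM (-3.02 ± 0.49, adjusted p = 1.98e-07) and Lgals9 to 22.9 ± 4.6. Interferon response genes fell in 23 of 24 (23 adjusted over the list alone). Oas3 fell to 0.849 ± 0.183 CPM (-3.55) and Gbp2 to 3.69 ± 2. By edgeR 12691 genes passed, 6890 higher and 5801 lower, and 11730 to 11930 with 1 library left out. Camera passed 0 of 38 lists, with 2 at unadjusted p under 0.05 (basal adjusted p = 0.282, attractant 0.567, checkpoint 0.653, neutrophil and interferon 0.885).

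In 4T1 (n = 5) 2 granzymes were among the 6 named increases. The granzymes Gzmg (98.9 ± 61.1 CPM, 2.07 in 2224; 11.67 ± 0.72, adjusted p = 2.18e-21) and Gzmf (94.1 ± 53.7, 1.66 in 2224) rose. Gpa33, an intestinal surface antigen (chr1 166130238-166166510), averaged 186 ± 20.1 CPM against 2.21 in MMTV-PYMT (10.72 ± 0.32, adjusted p = 4.39e-42), the protease Tmprss11e 115 ± 23 against 0.983 in 9263, the bone matrix gene Ibsp 20.6 ± 7.41 against 0.286 in 2208 (9.35 ± 0.51) and the annotated pseudogene Kdm4dl 21.9 ± 2.51. The glutathione peroxidase Gpx2 (0.00762 CPM, 329 in 2250; -10.71 ± 1.22, adjusted p = 6.28e-12), Wfdc18 (0.248, 2880 in 2208) and Sox10, a regulator of basal-like cells (0.329 ± 0.465; -9.25 ± 0.46, adjusted p = 2.44e-29), fell, and Slc6a14 had 0 counts (bound 0.00634 CPM). Cdkn2a, which holds the p16 and Arf inhibitors (chr4 89274471-89294653) and was read later, was at 0.275 CPM in 4T1 and 0.217 in E0771 against 4.02 (MMTV-NEU) to 197 CPM (T12) elsewhere.

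Neutrophil genes rose in 16 of 18 and fell in 2 in 4T1 (16 and 2 adjusted over the list alone). Mmp9 rose to 180 ± 63.6 CPM (4.45 ± 0.37, adjusted p = 2.81e-17, 35.7 in 2224). Neutrophil attractants rose in 10 of 11 (10 adjusted over the list alone). Csf3 rose to 29.3 ± 5.72 CPM (5.07 ± 0.33, adjusted p = 8.56e-23, 22.1 in 2153), Csf2 to 1.68 ± 0.665 and Il1b to 60.7 ± 14. Class II genes rose in 9 of 10 (9 adjusted over the list alone). Cd74 rose to 1190 ± 623 CPM (2.46 ± 0.43) and H2-DMa to 79.9 ± 31. Checkpoint genes rose in 11 of 13 and fell in 1 (11 and 1 adjusted over the list alone). Tigit rose to 3.73 ± 0.953 CPM (4.35). Proliferation genes fell in 23 of 24 (24 adjusted over the list alone). The mitotic kinase Aurka fell to 23.8 ± 5.23 CPM (-1.58 ± 0.17, adjusted p = 1.13e-12) and Tpx2 to 61.5 ± 14.6. By edgeR 11222 genes passed, 5830 higher and 5392 lower, and 10229 to 10372 with 1 library left out. None of the 38 lists passed camera with estimated correlation and 3 had unadjusted p under 0.05 (attractant adjusted p = 0.159, checkpoint 0.206, neutrophil 0.331, class II and proliferation 0.731).

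In 9263 (n = 7) 2 keratin genes were among the 6 named increases. The hair root keratins Krt26 (chr11 99328550-99337966; 155 ± 151 CPM, 22.2 in MMTV-PYMT; 12.43 ± 0.75, adjusted p = 2.69e-19) and Krt73 (chr15 101793308-101802346; 345 ± 378, 93.9 in the next model; 11.30 ± 0.73) rose with the hair genes Prr9 (197 ± 159, 107 in the next model) and Tchhl1 (46.7 ± 42.5, 30.4 in the next). Dkk4 averaged 43.7 ± 41.9 CPM (12.25 ± 0.41, adjusted p = 3.91e-29) and the isoprenoid enzyme Idi2 171 ± 133 CPM against 1.31 in MMTV-PYMT (12.23 ± 0.39, adjusted p = 1.34e-40). The motor gene Myo5c (0.172 CPM, 118 in MMTV-NEU; -6.43 ± 0.38, adjusted p = 3.49e-25), the protease Tmprss2 (0.0653 CPM, 86.1 in 2250; -6.30 ± 0.36, adjusted p = 6.34e-26), Igfals (-6.03, 154 CPM in MMTV-NEU) and Adcy8 (0.00421 CPM, 66.5 in 2153) were low.

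Wnt genes rose in 14 of 16 in 9263 (14 adjusted over the list alone). The inhibitor Wif1 rose to 502 ± 174 CPM (7.08 ± 0.41, adjusted p = 8.26e-26, 85.1 in 2224) and Notum to 84.9 ± 37.5 (6.54, 35.5 in 4T1), both targets of the pathway, and Wnt6 to 71 ± 32.4. Basal genes rose in 15 of 18 and fell in 1 (15 and 1 adjusted over the list alone). Krt5 rose to 701 ± 64.7 CPM (5.97), Krt15 to 206 ± 52.1 and the contractile gene Cnn1 to 329 ± 109 (5.79 ± 0.34, adjusted p = 4.02e-25, 116 in T12). All 17 squamous genes rose (17 adjusted over the list alone). Sprr1a rose to 231 ± 197 CPM (8.34 ± 0.64, 83.9 in MMTV-PYMT) and Krtdap to 36.1 ± 22.7. Proliferation genes rose in 17 of 24 (17 adjusted over the list alone). Aurkb rose to 121 ± 28.4 CPM (1.23 ± 0.10) and Top2a to 562 ± 120. By edgeR 12440 genes passed, 7427 higher and 5013 lower. Camera passed the Wnt list (adjusted p = 0.0274) and not the basal (0.0971), squamous (0.225) or proliferation (0.941) lists. The Wnt call ended with the authors' table (0.0694), the same-strain reference (0.0576) and without T12 and E0771 (0.103). Under both changed references its unadjusted camera p hardly moved (0.000596 and 0.000494, against 0.000406). Those losses came from the adjustment over the other lists.

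The named increases in E0771 (n = 3) included Esx1, Pnma5 and Tex19.1. Esx1, a placental homeobox gene (chrX 137115397-137122083), averaged 506 ± 42.3 CPM against 1.79 in 2336 (12.63 ± 0.40, adjusted p = 2.3e-38). Pnma5 averaged 219 ± 9.51 CPM against 0.15 in MMTV-NEU (12.49 ± 0.34, adjusted p = 7.99e-44), the germ line transposon silencer Tex19.1 93.1 ± 22.1 against 0.0608 in 2336 (12.23 ± 0.32, adjusted p = 3.56e-46), the RNA export gene Nxf3 72.8 ± 2.34 (13.52 ± 0.34), the pluripotency gene Dppa4 34.6 ± 1.77 against 0.00383 in MMTV-PYMT and Rhox2h 12.2 ± 0.725 CPM. Dppa4 and Rhox2h lost the call with DESeq2 (adjusted p = 0.127 and 0.159) and with library number as a block (1 for both). The casein Csn3 was at 0.0206 CPM against 23600 in MMTV-NEU (-12.53), Wfdc18 at 0.0794 and Slc6a15 at 0.0057 (291 in 2153), and the cartilage collagen Col9a2 had 0 counts (bound 0.0149 CPM, 403 in 2336).

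Junction genes fell in 18 of 20 and luminal genes in all 19 in E0771 (18 and 19 adjusted over the list alone). Krt18 fell to 0.593 ± 0.605 CPM (-9.72 ± 0.59, adjusted p = 1.72e-24). All 24 interferon response genes rose (24 adjusted over the list alone). The T cell attractant Cxcl10 rose to 107 ± 18.4 CPM (4.60 ± 0.42, adjusted p = 8.35e-16, 20.8 in 2208), Oas3 to 138 ± 24.7 and Usp18 to 137 ± 31.7. T cell genes rose in 17 of 19 and natural killer genes in 12 of 13 (17 and 12 adjusted over the list alone). Cd8a rose to 15.2 ± 13.6 CPM (5.10 ± 0.53, 3.41 in T12) and Ccl5 to 59.1 ± 16.9 (4.81 ± 0.30, adjusted p = 5.19e-24, 7.72 in 2250). All 15 muscle genes rose (15 adjusted over the list alone; 11 without replicate 1). Acta1 rose to 634 ± 430 CPM (4.72 ± 1.23, adjusted p = 0.000746) and Ckm to 189 ± 138. By edgeR 12878 genes passed, 6722 higher and 6156 lower, and 11021 to 11317 with 1 library left out. Camera passed the junction list (adjusted p = 0.0374), and the luminal (0.0598; 0.00216 with the authors' table, a call gained), T cell (0.377), natural killer (0.419), interferon (0.709) and muscle (0.877) lists did not pass.

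The named increases in KPB1-A (n = 2) included Nr1h5 and Cntn1. Nr1h5, a sterol-binding nuclear receptor (chr3 102939658-102964133), averaged 123 ± 65.5 CPM against 13.1 in MMTV-PYMT (11.74 ± 0.35, adjusted p = 3.87e-41) and the neuronal adhesion gene Cntn1 86.5 ± 13.7 against 0.315 in 2336 (10.72 ± 0.36, adjusted p = 9.61e-39). Upk3a, a urothelial membrane gene (62.1 ± 51.3 CPM, 6.86 in 2225; 10.83 ± 0.48), Rimklb (28.6 ± 11.4) and Psg29 (6.59) rose. Afm, a serum carrier of the liver (chr5 90518932-90553543), averaged 23.4 ± 3.7 CPM against 0.0055 in 4T1 and lost the call with DESeq2 (adjusted p = 0.101) and with the block (1). Ifi44 fell to 0.715 ± 0.141 CPM (6.41 to 138 elsewhere; -5.73 ± 0.91, adjusted p = 2.31e-07), with Ifit3b (-6.41), Cd300lh (-7.40) and the lipid gene Thrsp (0.0773 CPM, 370 in MMTV-PYMT).

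Hormone sensing genes rose in 9 of 16 and fell in 2 in KPB1-A (9 and 2 adjusted over the list alone). The oestrogen receptor partner Foxa1 rose to 173 ± 33.4 CPM (6.42 ± 0.42, adjusted p = 4.85e-22, 57.8 in 2153), the progesterone receptor Pgr to 19.6 ± 9.36 (5.19 ± 0.52, 7.91 in 9263) and Cited1 to 32.1 ± 21.6. Mast cell genes rose in 7 of 10 (9 adjusted over the list alone). The tryptase Tpsab1 rose to 95.6 ± 26.9 CPM (6.44 ± 0.57, adjusted p = 6.26e-16, 25.3 in 4T1) and Mcpt4 to 40.8 ± 23.1. Basal genes rose in 13 of 18 (13 adjusted over the list alone). The stem cell receptor Lgr5 rose to 86.8 ± 39.7 CPM (6.94 ± 0.37, adjusted p = 3.36e-27, 9.88 in the next model) and Krt5 to 1210 ± 288. Interferon response genes fell in 18 of 24 (19 adjusted over the list alone). Usp18 fell to 0.259 and Oas2 to 0.81 CPM, and 13 or 11 fell when either library was left out. By edgeR 8965 genes passed, 5680 higher and 3285 lower, against 5987 and 6032 with the other library alone. Camera passed 0 of 38 lists, with 3 at unadjusted p under 0.05 (hormone sensing adjusted p = 0.154, mast cell 0.159, basal 0.223, interferon 0.918).

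Caseins were among the named increases in MMTV-NEU (n = 8). The caseins Csn1s2a (chr5 87774567-87788797; 4560 ± 3690 CPM, 46.9 in MMTV-PYMT; 16.53 ± 0.33, adjusted p = 4.22e-49), Csn2 (chr5 87692624-87699630; 4460 ± 3880, 486; 12.69 ± 0.50, adjusted p = 6.69e-35) and Csn1s1 (7690 ± 6680, 178; 12.14 ± 0.44, adjusted p = 2.44e-36) rose with Csn1s2b (31.2 ± 28, 0.536), the mammary noncoding RNA Pinc (178 ± 186, 39.7) and the milk amino acid oxidase Lao1 (141 ± 111, 211). Hmga2, an oncofetal chromatin gene, fell to 0.129 CPM (523 in T12; -7.59 ± 0.42, adjusted p = 7.45e-27), as did the fetal RNA-binding gene Igf2bp1 (0.00194, 74.3 in 2208) and Krt15 (0.0873, 206 in 9263). Nf1, a tumour suppressor (chr11 79339693-79581612) read later, was at 670 ± 336 CPM against 65.7 to 128 in the other models (2.90 ± 0.12).

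Milk genes rose in 14 of 15 in MMTV-NEU and fatty acid synthesis genes in all 14 (14 and 14 adjusted over the list alone). The lipogenic regulator Srebf1 rose to 2390 ± 1280 CPM (3.40 ± 0.13, adjusted p = 6.14e-37, 879 in MMTV-PYMT) and Scd1 to 2820 ± 1090. ERBB genes rose in 9 of 13 and fell in 4 (9 and 4 adjusted over the list alone). The receptor Erbb4 rose to 47 ± 22.3 CPM (8.95 ± 0.36, adjusted p = 6.29e-32, 6.04 in MMTV-PYMT) and the ligand Btc to 9.7 ± 2.39 (2.40), while the ligand Ereg fell to 0.207 (-2.99). Proliferation genes fell in 22 of 24 (22 adjusted over the list alone). Birc5 fell to 42.8 ± 13 (-1.22) and Aurkb to 26.2 ± 8.75 CPM (-1.16). All 14 adipocyte genes rose (14 adjusted over the list alone). The lipid droplet gene Plin1 rose to 14.1 ± 16.2 CPM (4.78). By edgeR 14261 genes passed, 7775 higher and 6486 lower. None of the 38 lists passed camera with estimated correlation and 5 had unadjusted p under 0.05 (milk and ERBB adjusted p = 0.0707, milk 0.0266 and passing with the authors' table, fatty acid 0.251, proliferation 0.789, adipocyte 0.976).

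Wap and Lao1 were among the named increases in MMTV-PYMT (n = 5). Wap, a whey protein, averaged 82.9 ± 123 CPM against 42.1 in the next model (11.22 ± 0.50, adjusted p = 4.25e-31) and Lao1 211 ± 192 (12.87 ± 0.45). The secretoglobins Scgb2b27 (chr7 34011921-34013942; 303 ± 609 CPM, 38.2 in the next model; 12.62 ± 0.48) and Scgb1b27 (69.1 ± 148, 0.332 in MMTV-NEU), Mup5 (25.1 ± 55.6) and Prol1 (16.8 ± 28.7, 13.7) were high with SDs above their means. Replicate 2 carried most of these levels, and without it Scgb1b27 went from 13.36 to 8.84, Scgb2b27 to 9.30, Mup5 to 5.13 and Prol1 from 10.78 to 8.72, all still passing. The transcription factor Gata4 (37.1 CPM in 2208) and the mast cell protease Mcpt2 (54.6 in KPB1-A) had 0 counts (bound 0.0117 CPM), and Cd300lh was at 0.0149.

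All 20 junction genes rose in MMTV-PYMT (20 adjusted over the list alone). Cldn1 rose to 216 ± 62.1 CPM (4.08 ± 0.17, adjusted p = 7.9e-34, 118 in 2250) and the polarity gene Crb3 to 28.1 ± 5.63 (2.85). Luminal genes rose in 18 of 19 and milk genes in 14 of 15 (18 and 15 adjusted over the list alone). Krt19 rose to 214 ± 261 (5.19 ± 0.47), Ehf to 1040 ± 337 (4.62 ± 0.23) and Csn2 to 486 ± 540 CPM (9.23). Squamous genes rose in 15 of 17 and fell in 1 (15 and 1 adjusted over the list alone; 9 rose without replicate 1), and Sprr1a (83.9 ± 183 CPM) was at 1.31 with adjusted p = 0.116 without that library. Krt5 (103 ± 157 CPM, 2.97) likewise went to 1.43 (adjusted p = 0.0692). Proliferation genes fell in 19 of 24 (20 adjusted over the list alone; 14 without replicate 4). Cdk1 fell to 55.7 ± 16.6 CPM (-1.23 ± 0.17) and Bub1 to 21.4. By edgeR 11756 genes passed, 7075 higher and 4681 lower, 10737 to 10981 with 1 library left out and 7184 with the same-strain reference. Camera passed the junction, milk and luminal lists (adjusted p = 0.0274 each) and not the squamous (0.946) or proliferation (0.841) lists. These calls ended with the same-strain reference (junction 0.168, milk 0.456, luminal 0.406) and without T12 and E0771 (0.563, 0.103, 0.746). Without T12 and E0771 the unadjusted camera p of the milk list hardly moved (0.000248 against 0.000247). That loss came from the adjustment over the other lists.

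The named increases in T12 (n = 3) included Grid1 and Onecut2. Grid1, a glutamate receptor gene (chr14 34820108-35583379), averaged 33.7 ± 4.41 CPM against 5.31 in 2225 (10.72 ± 0.31, adjusted p = 4.7e-38) and Onecut2, a liver and neuron transcription factor (chr18 64340020-64400987), 96.5 ± 15.9 against 9.83 in KPB1-A (9.97 ± 0.32, adjusted p = 1.64e-40). Rgs17 (50.2 ± 7.67 CPM, 0.322 in 9263; 10.70 ± 0.34), the orphan receptor Gpr149 (18.9 ± 6.9, 3.45 in E0771), Ndst4 (7.58) and Sp8 (5.64) were high. The collagen Col9a1 (chr1 24177610-24252684), the imprinted gene Phlda2 (43 in 2153) and the muscle myosin Myh4 (adjusted p = 0.042) had 0 counts (bound 0.0125 CPM), and Faim2 was at 0.0082 CPM (334 in 2250).

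Junction genes fell in 19 of 20 and rose in 1 and all 19 luminal genes fell in T12 (19, 1 and 19 adjusted over the list alone). Ocln fell to 0.0196, Dsp to 0.333 and the epithelial splicing gene Esrp1 to 0.129 ± 0.152 CPM. Transition genes rose in 14 of 22 and fell in 1 (14 and 1 adjusted over the list alone), the Cdh1 repressor Zeb1 to 175 ± 17.8 CPM (3.96 ± 0.21, adjusted p = 7.57e-28, 75.9 in E0771), Prrx1 to 256 ± 39.3, Itga5 to 592 ± 58.4 (3.40, 271 in the next model) and Foxc2 to 36.8 ± 1.88 (4.04, 33.5 in 4T1). Macrophage genes rose in 14 of 18 and natural killer genes in 12 of 13 (14 and 12 adjusted over the list alone). The mannose receptor Mrc1 rose to 578 ± 107 CPM (3.97 ± 0.41, 181 in 4T1), Lyz2 to 3020 ± 201 (3.35, 1750 in the next model), Csf1r to 524 ± 86.6 and Ncr1 to 2.53 ± 0.405. By edgeR 11023 genes passed, 5578 higher and 5445 lower, and 9034 to 9225 with 1 library left out. Camera passed the junction and luminal lists (adjusted p = 0.0274 for both) and not the transition (0.714), macrophage (0.777) or natural killer (0.709) lists, and both calls ended with the same-strain reference (0.0518 for both).

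**Figure D3:**
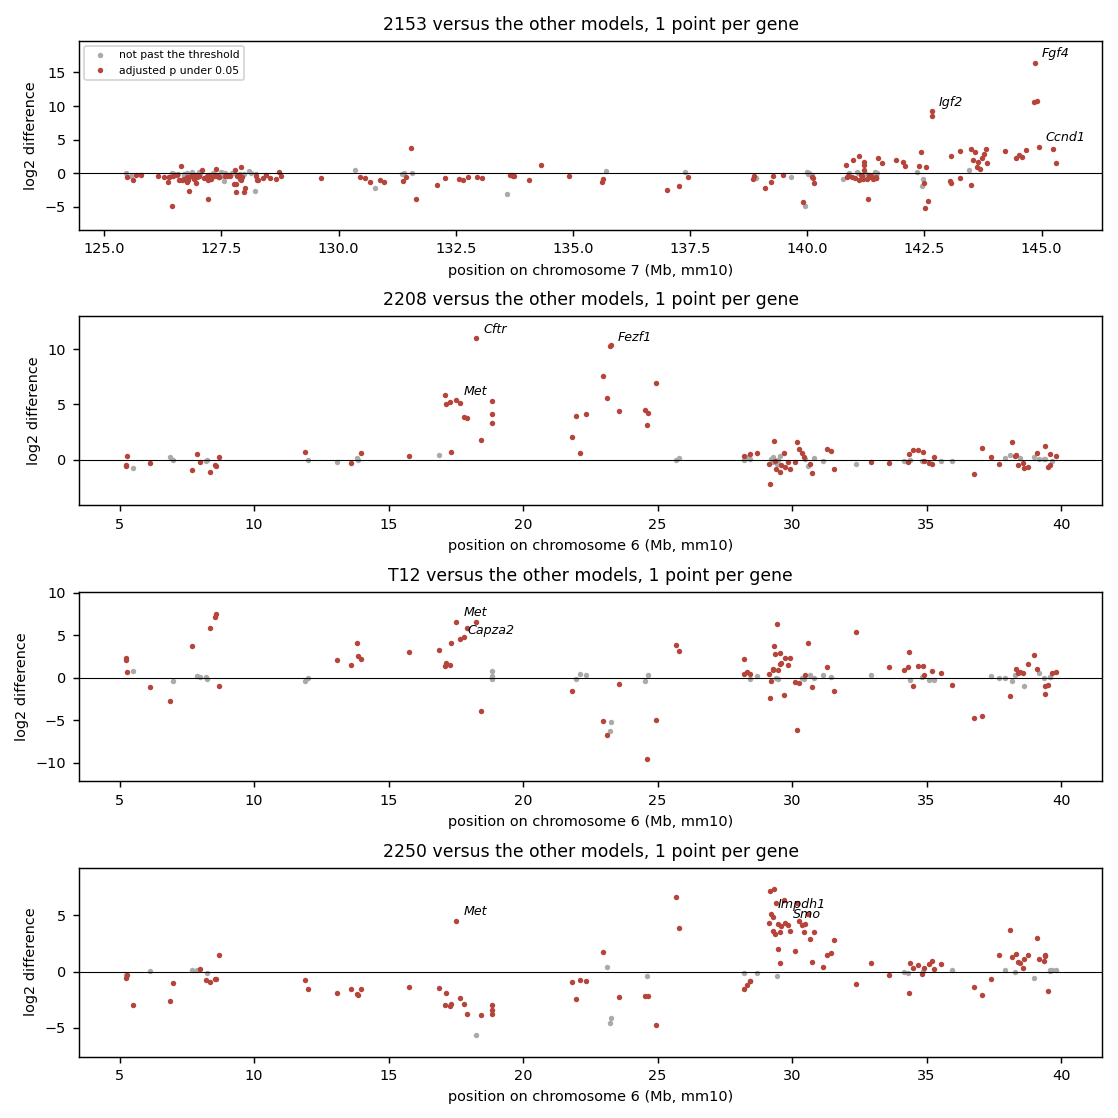
Log2 difference of each gene with a mean of at least 1 CPM (vertical axis) by position in mm10 (horizontal axis, Mb) for 2153 on chr7 and for 2208, T12 and 2250 on chr6, each point a gene and red where adjusted p was under 0.05. Fgf4 rose by 16.47 in 2153, and Met by 5.40 in 2208, 6.60 in T12 and 4.53 in 2250.

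MMTV-NEU (n = 8) and MMTV-PYMT (n = 5), 2 FVB models named for different oncogenes under 1 promoter, differed first in Erbb2 itself, at 11900 ± 3910 against 80.3 ± 19.4 CPM (7.22 ± 0.22, adjusted p = 4.67e-41). Comp, a cartilage matrix gene (181 ± 136 against 0.799 CPM; 7.81 ± 0.77, adjusted p = 8.3e-13), the protocadherin Pcdh10 (185 ± 92.5 against 1.19; 7.27 ± 0.60, adjusted p = 9.31e-16), the casein Csn1s2a (6.60 ± 0.61, adjusted p = 2.72e-13), the mitochondrial carrier Slc25a34 (286 ± 155 against 9.08; 4.98 ± 0.69, adjusted p = 3.16e-08) and Cldn10 (57.6 against 1.84) were also higher in MMTV-NEU, with Trim9 (6.09), Csn1s2b (5.86), Efhd1 (4.97) and Mfsd7c (4.95). Higher in MMTV-PYMT were the kallikreins Klk7 (chr7 43811294-43816359; 0 against 37.1 CPM, MMTV-NEU bound 0.00725), Klk10 (0.477 ± 0.877 against 118; -7.92 ± 0.91, adjusted p = 1.35e-10) and Klk6 (-7.07), the keratins Krt79 (0.462 against 50.3; -6.91 ± 0.72, adjusted p = 5.66e-12), Krt15 (0.0873 against 18.2; -8.18 ± 0.90) and Krt75 (0 against 5.46), and Dsc3 (-7.22) and Elovl4 (-6.26). Without MMTV-PYMT replicate 1 Krt75 was at -6.14, Krt79 at -4.86, Klk6 at -4.59, Dsc3 at -4.54 and Elovl4 at -3.85, all still passing. Saa2, an acute phase gene, was at 1.61 ± 2.02 against 114 CPM (-6.18 ± 0.83, adjusted p = 1.26e-08).

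**Figure D4:**
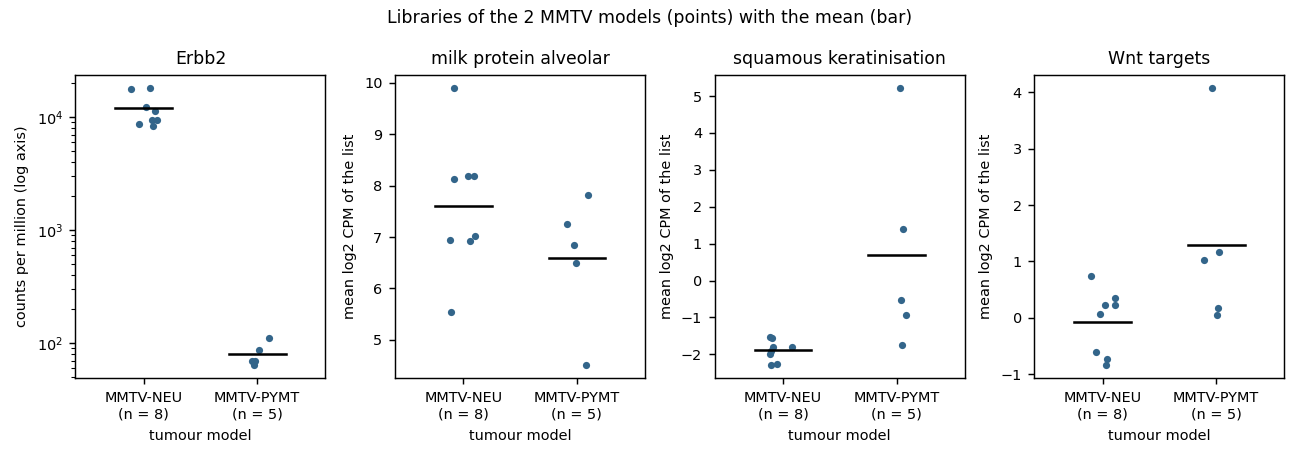
Erbb2 (CPM, log axis) and the milk, squamous and Wnt scores (mean log2 CPM) in each library of MMTV-NEU (n = 8) and MMTV-PYMT (n = 5), 1 point per library and a bar at the mean. Squamous scores ran from -1.74 to 5.21 in MMTV-PYMT and from -2.28 to -1.52 in MMTV-NEU.

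Squamous genes were lower in MMTV-NEU than in MMTV-PYMT in 14 of 17 (15 adjusted over the list alone; 10 without MMTV-PYMT replicate 1). Krt6a was at 0.044 against 63.9 ± 140 CPM (-10.23), mostly from MMTV-PYMT replicate 1, and at -4.89 (adjusted p = 0.000111) without it. Wnt genes were lower in 12 of 16 (12 adjusted over the list alone; 6 without MMTV-PYMT replicate 1), the feedback gene Axin2 at 1.04 ± 0.788 against 48.2 ± 61.8 CPM (-5.65 ± 0.58, adjusted p = 4.06e-12). Targets of p53 were lower in 8 of 18 and higher in 1 (11 and 1 adjusted over the list alone). Aen was at 20.5 ± 7.37 against 51.9 ± 13.2 CPM (-1.34 ± 0.18, adjusted p = 1.5e-08), Sesn2 at 13.1 ± 3.52 against 30.7 ± 6.25 (-1.23) and Cdkn1a at 37.9 ± 27.2 against 88.4 ± 42.3 (-1.22; adjusted p = 0.0822 in a fit of only the 2 models). ERBB genes were higher in 5 of 13 and lower in 2 (6 and 4 adjusted over the list alone). Erbb4 was at 47 against 6.04 ± 3.08 CPM (2.96 ± 0.56, adjusted p = 3.4e-05) and the ligand Hbegf at 5.17 ± 3.05 against 24.6 ± 19.1 (-2.25). Immediate early genes were lower in 8 of 15 and higher in 1 (10 and 2 adjusted over the list alone; 6 lower without MMTV-PYMT replicate 4 and 5 without replicate 5). Fosl1 was at 1.34 against 7.87 ± 5.84 CPM (-2.57) and Egr2 at 2.48 against 9.24 ± 5.92. By edgeR 6318 genes passed, 2865 higher and 3453 lower, against 2880 in a fit of only the 2 models and 5262 to 5996 with 1 library left out. Camera passed 0 of 38 lists, with 3 at unadjusted p under 0.05 (p53 adjusted p = 0.055, ERBB 0.0886, Wnt 0.709, immediate early 0.789, squamous 0.841).

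T12 (n = 3) and 2225 (n = 10), both BALB/c, were compared next as examples of the claudin-low and basal-like classes, which the labels assign to neither. All T12 library numbers are below 3000 and all 2225 ones above it. Library number thus could not be separated from model here, and the block takes its shift from other models. Higher in T12 were Gap43, of growing axons, at 80.1 ± 18.4 against 0.0216 CPM (11.77 ± 0.80, adjusted p = 8.33e-22) and Stmn2, a microtubule regulator (chr3 8509360-8561606), at 150 ± 26.6 against 0.0535 (11.42 ± 0.93, adjusted p = 5.66e-18), with the transcription factor Tbx20 (42.4 ± 5.85 against 0.00522), Dynap (67.7 ± 11.7 against 0.0129), Adcy8 (39.8 against 0.00786), Slc9a2 (29.6 against 0.00416), Rgs17 (50.2 against 0.018), and Gpr149 (18.9) and Ndst4 (7.58), both at 0 in 2225 (bound 0.00525 CPM). Higher in 2225 were the traffic gene Rab17 (0.00723 against 115 CPM; -13.51 ± 0.96, adjusted p = 8.84e-21), Brinp2 (0.00723 against 175), Faim2 (0.0082 against 77.3; -12.93 ± 0.85, adjusted p = 2.68e-22), and Col9a1 (68.8), the Wnt receptor Fzd10 (35.8), the basal-like marker Gabrp (34.3), Ptgds (22.1), Serpina9 (22.1), Foxi3 (17) and Gjb1 (16.5), all 7 at 0 in T12 (bound 0.0125 CPM).

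Junction genes were lower in T12 than in 2225 in 18 of 20 and luminal genes in all 19 (19 and 19 adjusted over the list alone). Cldn3 was at 0.0915 against 291 ± 67.7 CPM (-11.62 ± 0.76), Cldn4 at 0.199 against 239 ± 46.4, Elf3 at 0.115 against 147 and Esrp1 at 0.129 against 165 ± 10.3. Transition genes were higher in 13 of 22 and lower in 2 (13 and 2 adjusted over the list alone). Fn1 was at 5340 ± 1010 against 311 ± 121 CPM (4.10 ± 0.52), Tgfbi at 348 ± 31.6 against 11 ± 2.5 (4.98 ± 0.44, adjusted p = 1.8e-16) and Zeb1 at 175 against 7.59 ± 1.27 (4.53 ± 0.31). Macrophage genes were higher in 16 of 18 and natural killer genes in 12 of 13 (16 and 12 adjusted over the list alone). Adgre1 was at 162 ± 21.7 against 6.85 ± 2.88 CPM (4.57 ± 0.48), Lyz2 at 3020 against 141 ± 37.2, Mrc1 at 578 against 31.5 and Gzmb at 5.4 ± 3.07 against 0.125. By edgeR 13277 genes passed, 6134 higher and 7143 lower, and 11884 to 11910 with 1 library left out. Camera passed the junction (adjusted p = 0.0274) and luminal (0.0374) lists and not the transition (0.789), macrophage (0.75) or natural killer (0.584) lists.

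4T1 (n = 5) and E0771 (n = 3), transplantable lines of different strains, were the last pair. Keratin 18, Krt18, was at 1060 ± 84 CPM in 4T1 and 0.593 in E0771 (10.83 ± 0.63, adjusted p = 4.94e-25). Gpa33 (186 ± 20.1 against 0.0593; 11.56 ± 1.10, adjusted p = 1.33e-14), Tmprss11e (115 against 0.00944; 13.24 ± 1.51, adjusted p = 1.9e-11), Hhip (92.5 ± 33.1 against 0.0179; 12.07 ± 1.20, adjusted p = 1.29e-13), Gzmg (98.9 against 0.00893), Kdm4dl (21.9 against 0.00447) and H2-Q2, a class I gene of the strain-variable H2 locus (37.4 ± 10.7 against 0.0146; 11.11 ± 0.65, adjusted p = 1.23e-24) were higher in 4T1, and Ifi44l (12.9 ± 4.77), Slc22a29 (7.16), Rasef (6.43) and Rhox4a2 (5.54) were at 0 in E0771 (bound 0.0149 CPM). Esx1 (0.0018 against 506; -16.92 ± 1.06, adjusted p = 4.26e-22), Pnma5 (0.0341 against 219; -12.50 ± 0.85, adjusted p = 3.84e-21), the germ line gene Tdrd1 (0.00192 against 33.2), Nxf3 (72.8), Rhox2d (16.2) and Rhox2g (10.5) were higher in E0771, the last 3 at 0 in 4T1 (bound 0.00634 CPM). Dppa4, Rhox2h, Rhox1 and Luzp4 were also at 0 in 4T1 and lost the call with DESeq2 (adjusted p = 0.225, 0.26, 0.0611 and 0.195).

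Junction genes were higher in 4T1 in 17 of 20 and lower in 1 and luminal genes higher in 18 of 19 (17, 1 and 18 adjusted over the list alone). Epcam was at 366 ± 114 against 0.948 CPM (8.58 ± 0.38) and Cldn4 at 243 ± 131 against 0.507. Neutrophil attractants were higher in 8 of 11 (9 adjusted over the list alone). Csf3 was at 29.3 against 0.0531 CPM (9.03 ± 1.10). Targets of p53 were lower in 12 of 18 and higher in 2 (12 and 2 adjusted over the list alone). The stress factor Gdf15 was at 0.669 ± 0.169 against 21.4 ± 4.89 CPM (-4.99 ± 0.58), Sesn2 at 9.72 against 48.8 and Gtse1 at 10 against 58.9, while Perp was higher (79.9 ± 10.7 against 4.84 ± 8.03; 4.04, and 8.62 without E0771 replicate 2). Cholesterol synthesis genes were lower in 17 of 18 (18 adjusted over the list alone). Fdps was at 51.3 ± 9.26 against 200 ± 33.2 CPM (-1.96 ± 0.30) and Mvd at 13.2 against 48.6. T cell genes were lower in 15 of 19 (16 adjusted over the list alone; 10 without 4T1 replicate 1 and 5 without E0771 replicate 2). Cd8a was at 1.77 ± 2.17 against 15.2 ± 13.6 CPM (-3.11 ± 1.02, adjusted p = 0.00906; -2.09, adjusted p = 0.126 without E0771 replicate 2). By edgeR 10510 genes passed, 5138 higher and 5372 lower, and 8814 to 10095 with 1 library left out. Camera passed the junction list (adjusted p = 0.0428) and not the luminal (0.0546; 0.00334 with the authors' table, a call gained), p53 (0.198), attractant (0.451), cholesterol (0.693) or T cell (0.789) lists.

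Across the 608 pairs of list and comparison, 13 passed camera with estimated correlation, 61 had unadjusted p under 0.05 and 181 passed with the preset correlation. All calls but 2 were of the luminal or junction lists: luminal in 2208, 2250, MMTV-PYMT, T12 and T12 against 2225, and junctions in 2208, E0771, MMTV-PYMT, T12, T12 against 2225 and 4T1 against E0771. The other 2 were the Wnt list in 9263 and the milk list in MMTV-PYMT. The luminal and junction lists share Cldn3, Cldn4, Cldn7, Cdh1 and Epcam, so their calls in the same comparison are not independent. Lists in no paragraph above had their lowest adjusted p at 0.379 for B cells (T12, 7 of 13 higher), 0.877 for plasma cells (2153, 4 of 10 lower), 0.762 for dendritic cells (E0771, 9 of 12 higher), 0.92 for endothelium (4T1, 10 of 16 higher), 0.934 for fibroblasts (MMTV-PYMT, 6 of 18 lower and 1 higher), 0.976 for blood cells (2250, 7 of 10 lower), 0.836 for DNA repair (4T1, 12 of 18 lower and 1 higher), 0.331 for monocyte attractants (E0771, 9 of 11 higher and 1 lower), 0.976 for hypoxia (MMTV-NEU against MMTV-PYMT, 4 of 18 lower), 0.36 for Notch targets (2224, 9 of 13 higher) and 0.451 for heat shock (MMTV-NEU against MMTV-PYMT, 7 of 12 lower). With the same-strain reference camera passed 0 of 456 pairs, which held 9 of the 13 calls. There 46 had unadjusted p under 0.05 and the lowest adjusted p was 0.0518.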

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

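The muscle and adipose explanation for MMTV-PYMT replicate 5 and the weighing of the chromosome regions and muscle genes were chosen after seeing the results. Within models of 4 to 10 libraries, a library was singled out when its gap to the nearest other library was over the Dixon limit. Of 376 tests of levels, scores and quality shares 30 (7.98%) passed, in 16 libraries, where chance alone passes about 1 in 20 groups.

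In 2153, replicate 1 lay apart from the other 6 in mitochondria-like pseudogene share (3.16%, others 1.97% to 2.33%), the share of the 10 largest genes (6.61%, 5.32% to 5.52%), Erbb2 (102 CPM, 149 to 163), Cldn7 (84.6 CPM, 146 to 168), the junction score (6.04, 6.37 to 6.61) and the milk score (0.85, 0.15 to 0.39). Replicate 2 of 2153 lay apart in Krt8 (1720 CPM, 1060 to 1320) and the immediate early score (6.12, 5.3 to 5.59), and replicate 3 in the muscle score (1.02, -2.38 to -1.97). In 2225, replicate 1 lay apart in mitochondria-like share (3.64%, 1.4% to 1.94%) and Cldn4 (351 CPM, 190 to 264), replicate 3 in the natural killer score (-1.83, -4.04 to -2.88) and the adipocyte score (0.54, -1.89 to -1.06), and replicate 8 in Pgr (2.3 CPM, 0.534 to 1.47). In 9263, replicate 1 lay apart in Cdh1 (468 CPM, 162 to 290), the DNA replication score (5.42, 5.93 to 6.21) and the immediate early score (6.06, 4.36 to 4.95). In 4T1, replicate 4 lay apart in Krt5 (2.62 CPM, 0 to 0.36), replicate 2 in Krt14 (88.4 CPM, 25.4 to 42.8) and the junction score (5.17, 4.37 to 4.57), and replicate 1 in the Wnt score (2.39, 1.69 to 1.86). In MMTV-PYMT, replicate 1 lay apart in Krt5 (374 CPM, 8.25 to 107), Krt14 (345 CPM, 8.3 to 97.5) and the Wnt score (4.07, 0.05 to 1.16), replicate 2 in Esr1 (1.28 CPM, 11 to 12.4), replicate 3 in the luminal score (7.89, 7.56 to 7.65) and replicate 4 in the DNA replication score (4.47, 5 to 5.17). In 2336, replicate 4 lay apart in the DNA replication score (5.57, 6.01 to 6.07) and the proliferation score (6.26, 6.77 to 6.9), and in MMTV-NEU, replicate 8 in the natural killer score (-3.56, -2.07 to -0.91).

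The chr7 genes of 2153 and the chr6 genes of 2208 rose with their neighbours. Within 1 Mb of the Fgf genes of 2153 all 12 other tested genes rose by a median of 3.23 (95th percentile of windows of this size 0.71). Around Cftr in 2208 25 of 28 rose and 1 fell, with a median of 3.75 (95th percentile 0.46). Several of these entries overlap another gene (Gm26793 with Fgf15, Gm15592 and Gm15595 with Cftr, others with St7) and are not independent neighbours. All protein-coding genes of both windows rose, by 1.59 (Dhcr7) to 3.95 (Ccnd1) in 2153 and 0.67 (Cav1) to 6.21 (Ankrd7) in 2208. A regional change would give this. Reads shared with a paralog do not account for Fgf4 and Cftr: Fgf4 reached at most 0.0274 CPM in libraries of 2224 and 2336, which express other Fgf genes, and the Abcc relatives of Cftr had a median of -0.36 in 2208. A copy number gain, a viral insertion or a change of chromatin could each give the pattern, and no DNA was measured to tell them apart.

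Skeletal muscle scores were high in E0771 (5.18 to 7.53) and 2224 (1.78 to 6.49), and in 2208 only in replicates 9, 10 and 11 (8.48, 5.55 and 6.86; the other 9 libraries -2.3 to 2.87). Single libraries of other models were as high (MMTV-PYMT replicate 5 at 7.6, MMTV-NEU replicate 6 at 7.39 and 9263 replicate 3 at 6.84). Muscle in the piece of tissue fits: 10 further muscle genes outside the list had median differences of 3.46 in E0771, 2.09 in 2208 and 2.49 in 2224, and over the 19 libraries of these models the 15 list members had a median pairwise correlation of 0.967. Within these models a part for library size cannot be excluded, since the muscle score had a Spearman rho of 0.482 with the total count (permutation p = 0.0381, 100000 permutations). Other models argue against depth alone. T12 (73.8 to 86.71 M counts) scored -2.94 to -2.8 and 4T1 (76.71 to 108.6 M) -0.85 to 3.89, whereas E0771 had 57.68 to 76.32 M. No biological explanation was tested.

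MMTV-PYMT replicate 5 was the only library closest to another model, correlating best with MMTV-NEU replicate 6 (r = 0.968). A wrong label does not account for it, since its Erbb2 was 68.8 CPM, 122-fold below the lowest MMTV-NEU library (8420 CPM), nor do low squamous genes, since its squamous score of -0.52 lay within the other MMTV-PYMT libraries (-1.74 to 5.21). Both libraries carried muscle genes (scores 7.6 and 7.39), and without 206 muscle and adipose genes the best correlation was with MMTV-PYMT replicate 3 (0.9685) and no longer with MMTV-NEU replicate 6 (0.968). The margins are small (0.0021 before and 0.00053 after) and below the 0.01 written beforehand as the bound for exclusion, so tissue content is a possible and not a proven cause.

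Random relabelings of the libraries were also counted, in 24 ways per comparison of models. The real grouping had the largest count in each (1 of the relabelings, itself, was as large): the highest other counts were 2570 for the F test, 689 for 2153, 2113 for 2208, 811 for 2224, 1627 for 2225, 1313 for 2250, 657 for 2336, 1168 for 4T1, 727 for 9263, 495 for E0771, 1632 for KPB1-A, 1847 for MMTV-NEU, 1214 for MMTV-PYMT and 1137 for T12. In fits of only the 2 models of a pair the highest other counts were 1 gene over 100 splits against 2880 genes (MMTV-NEU and MMTV-PYMT), 4 genes over 100 splits against 14288 (T12 and 2225) and 0 over 56 splits against 13232 (4T1 and E0771). Shuffled labels put the differences between models into the spread within groups, which lowers the counts. With 81 of 82 libraries closest to their own model, these counts do not bear on batch or on passages of a shared tumour.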

How the results depend on the processing

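The reference without T12 and E0771 was chosen after seeing several epithelial genes low in both. Other settings were planned. Of 188 counts of calls under an alternative 183 stayed within 1.5 times, and the other 5 were 7184 genes for MMTV-PYMT with the same-strain reference (11756 in the fit of all), 2880 for MMTV-NEU against MMTV-PYMT in a fit of only the 2 models (6318), and 181 (preset correlation), 0 (same strain) and 0 (without T12 and E0771) list shifts (13). Fewer libraries or reference models enter the first 2 fits. The cause was not tested further. The last 2 settings could test only 9 and 7 of the 13 calls, respectively. Of 6456 alternative values for 688 named results 6236 kept direction and side of the threshold, 133 lost the call, 41 gained it and 46 turned direction. By setting, the values that kept both numbered 674 of 688 with DESeq2, 681 with no filter, 686 with DESeq2 size factors, 679 with the block, 658 with limma on the authors' table, 474 of 525 with the same-strain reference, 430 of 482 without T12 and E0771, 110 of 118 with only the 2 models and all but 47 leaving out a library. In 45 values counted as kept the sign changed with neither value past the threshold. Leaving out the 2208 library without a number gave 12022 genes for 2208. The library number term itself passed for 3380 genes (14.8%).

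With the same-strain reference these turned direction: Trp53 (0.88), Cdh1 (-0.03) and Krt18 (-0.02) in MMTV-NEU; Cldn3 (-1.59), Cldn7 (-1.62), Epcam (-1.40), Cdh1 (-0.99), Krt18 (-0.13), Esr1 (-0.07), Egfr (-0.98) and Spdef (-1.41) in KPB1-A; Krt18 in 2336 (-0.66); Esr1 in 9263 (0.48) and MMTV-PYMT (-0.84); and Cldn8 in MMTV-PYMT (-0.05). Without T12 and E0771 in the reference these did: Erbb2 in 2208 (-0.14) and 2225 (-0.08); Cldn3 in KPB1-A (-0.94); Cldn4 in 2153 (-0.68), 2250 (-0.40), 9263 (-0.54) and MMTV-NEU (-0.25); Cldn7 in 4T1 (-1.50), 9263 (-1.32) and KPB1-A (-1.17); Epcam in 2208 (-0.06), 2224 (-0.44), 2336 (-0.76), 4T1 (-0.92), 9263 (-0.31) and KPB1-A (-0.59); Cdh1 in 2153 (-0.11), 2224 (-0.49), 2336 (-0.58), 4T1 (-0.98), 9263 (-0.38) and KPB1-A (-0.14); and Krt18 in 2224 (-0.42), 2336 (-1.44), KPB1-A (-0.25), MMTV-NEU (-0.17) and MMTV-PYMT (-0.04). The second reference drops the 2 models where these genes, Erbb2 apart, are far below the others and lower their mean. Erbb2 was also lowest in T12 (23.3 CPM) and E0771 (37.2 CPM), so its reference rose likewise. The cause was not tested for the turns with the same-strain reference, which drops other models for each strain. For KPB1-A that reference is MMTV-NEU and MMTV-PYMT (Epcam 1610 and 869 CPM), and for MMTV-NEU it holds KPB1-A (Trp53 17 CPM). With limma on the authors' table Krt5 in E0771 (-3.84) and Myh4 in 2208 (-0.28) turned, and leaving out a library Krt5 in E0771 ran from -12.85 to 0.99 and Cldn3 in KPB1-A from -0.32 to 1.57. The last 2 follow from single libraries, E0771 replicate 2 (Krt5 59.8 CPM, 0 in the others) and KPB1-A replicate 1 (Cldn3 182 against 48.8). The cause was not tested for the 2 values with limma. Cldn3 in KPB1-A (0.91, adjusted p = 0.0456) also lost its call with DESeq2 (0.0638), no filter (0.08) and the block (0.127).

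Camera passed 15 lists with the authors' table (12 of the 13 calls among them, and luminal in E0771 at 0.00216, luminal in 4T1 against E0771 at 0.00334 and milk in MMTV-NEU at 0.0266) and 13 with the block (all 13). The share of calls that were higher moved by over 10 points with limma on the authors' table: 43% against 54.4% (2208), 41.2% against 53.7% (2250), 46.2% against 59.7% (9263), 42.4% against 54.5% (MMTV-NEU), 43.3% against 60.2% (MMTV-PYMT) and 59.8% against 48.9% (4T1 against E0771). By smaller shifts most calls also turned from higher to lower in 2153 (47.7% against 55.5%), 2225 (49.4% against 56.1%), 2336 (44.9% against 54.3%) and E0771 (43.3% against 52.2%), and from lower to higher in T12 against 2225 (53.3% against 46.2%). Other settings that turned the majority were DESeq2 in 4T1 (48.6% against 52%), E0771 (47.3%), T12 (48% against 50.6%) and 4T1 against E0771 (52.3%), the same-strain reference in MMTV-NEU (47.6%) and T12 (49.4%), the reference without T12 and E0771 in 4T1 (48.6%), only the 2 models in T12 against 2225 (51.3%) and 4T1 against E0771 (50.2%), and DESeq2 size factors (50.5%), the block (52.3%) and no filter (5212 higher and 5211 lower) in 4T1 against E0771. DESeq2 also turned 2153 (6462 higher and 6464 lower). The median of all genes moved by over 0.1 for 9263 (-0.09 against 0.05), MMTV-NEU (-0.15 against -0.02), MMTV-PYMT (-0.11 against 0.04), T12 (0.02 against -0.09) and T12 against 2225 (0.01 against -0.11). No pairing was possible, as the labels carry no replicate numbers. Depth limits genes near the bounds of 0.00394 (2208) to 0.0348 CPM (KPB1-A) that 3 counts per model allow.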

Other observations

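The genes of the region scan and the relation of Nf1 to Erbb2 were chosen after seeing the results. Among genes in no comparison above, Xist, which silences an X chromosome, ran from 47.6 CPM in 2225 and 64.2 in 2250 to 2510 CPM in MMTV-NEU. Sox10 was near 0 in T12 (0.324 CPM), E0771 (0.156) and 4T1 (0.329) and at 445 to 1130 CPM in the other models. Cdkn2b, beside Cdkn2a on chr4, was at 1.07 CPM in 4T1 and 0.512 in E0771. In 2250 Tes and Cav1 beside Met fell by 2.94 and 2.89 while Met rose, and Impdh1 beside Smo was at 2390 ± 443 CPM. Capza2 was at 6530 ± 934 CPM in 2208 and 4380 ± 334 in T12, both in the reference for these falls.

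Runs of neighbouring genes moved together in several models. The scan used 14563 genes of at least 1 CPM in windows of 11 genes, against 100 permutations of gene order. In 2153 the run at chr7 142650766-145309557 held 30 genes, 25 of them higher, with a median of 2.66. On chr6, 2208 had 30 of 36 genes higher at 13867735-28398005 (median 4.05), T12 20 of 29 at 8255936-21852515 (2.14) and 2250 31 of 38 at 28219167-32588192 (3.51). In 2225, 34 of 44 genes were higher at chr1 169497934-171653035 (2.71) and 28 of 34 at chr1 74409376-78197134 (2.41), and 11 of 13 were lower at chr12 3235504-4477182 (-3.55), the run that holds Dnmt3a. In 2336, 48 of 50 genes were higher at chr8 20262613-27123436 (2.48), around Fgfr1, and in 2224 16 of 25 at chr10 116275523-120224917 (1.80), around Mdm2. Clusters of related genes (keratins, Hoxa genes, kallikreins, granzymes) also formed runs, so a run alone does not show a change of DNA.

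E0771 replicate 2 also had Krt14 at 43.1 CPM against 1.3 and 0.433 in the other 2 libraries, and a squamous score of 1.22 against -3.13 and -3.29. The first 4 principal components of the 1000 most variable genes held 24.6%, 18.3%, 11% and 6.72% of the variance. Squamous scores in 2224 averaged 1.26 ± 2.46 (n = 4).

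Nf1 varied from 219 to 1020 CPM over the 8 MMTV-NEU libraries. Against Erbb2, on the same chromosome, its r was -0.036 (exact p = 0.934 over 40320 arrangements), rho was 0.262 (exact p = 0.536), and r without the 2 farthest libraries was 0.413.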
